A study of Homo sapiens with 15 samples.

How the data were processed

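The values are probe intensities from 15 one-colour Illumina beadchips, 1 array per sample: 2 each of H9 hESC, BG02 hESC, H9 endoderm, H9 EB-derived cells, BG02 EB-derived cells and HCT116, and 3 of adult liver. Per the labels' protocols, RNA was extracted with Trizol, amplified and labelled with an Illumina TotalPrep kit and hybridised as 1 colour, Cy3. The deposited table holds each array's intensity values on a linear scale, with background already subtracted, as the values below 0 on 14 of 15 arrays show. The software, the slide, the date and any normalization between arrays are not given in the sources used here. The columns do not share a distribution, so the values had not been quantile normalized, while other scaling cannot be told from them, and HCT116 replicate 2 lies on a scale well below that of replicate 1. No detection p-values and no bead counts were used here, so signal over background sets the limit, and batches by slide or date were not tested.

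Groups and replicate numbers come from the sample titles. The title puts the BG02 EB samples in BG02 while another label of theirs names H9 hESCs as the starting cells, and the title was followed. The labels do not state which side of the CXCR4 gate the hESCs came from. CXCR4 is therefore no finding between sorted groups.

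Values were set to at least 0, 16 was added, log2 was taken, and arrays were quantile normalized. Fold changes are on the scale of log2(value + 16), which understates changes of dim genes, and a fold against a group at the background is compressed. A gene set to 0 in some groups hardly varies there, so its SE and p-value, from a spread shared by all groups, can be too small. Of 20589 probes 18026 have 1 gene symbol in the platform annotation, 0 have several and 2563 have none here, with 16365 different symbols, and the annotation can be old. XIST and Y-linked probes (39) were left out of everything, which leaves 20550 probes, tested without a filter. For a gene with more than 1 probe (1472 genes), the probe with the highest mean stands for the gene, and other probes are given where they disagreed.

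All groups were fitted in one linear model with limma (version 3.58.1, lmFit, and eBayes with a trend on the mean level; R version 4.3.3), with 8 residual degrees of freedom and a median prior of 4.19. All adjusted p-values of genes are limma's, two-sided, after Benjamini-Hochberg adjustment over 20550 probes. A probe counts as changed at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. There were 11 comparisons, each adjusted on its own: endoderm against hESC, EB-derived cells against hESC in each line and over both, the difference of the EB effect between lines (an interaction term), endoderm against EB-derived cells, BG02 against H9 before and after EB differentiation, liver against hESC and against endoderm, and HCT116 against hESC.

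The comparisons and their tests, the gene lists, the rule for named genes and all alternatives but 3 were fixed before the data were examined. The 26 lists hold 602 genes, 542 of them on the array: pluripotency, primitive streak and mesendoderm, definitive endoderm, Nodal targets, visceral and yolk sac endoderm, trophoblast, neural ectoderm, neural crest, mesenchyme and matrix, cardiac muscle, endothelial and blood, immune cells, secreted hepatocyte products, hepatocyte metabolism, liver transcription factors, colon epithelium and tumour, cell cycle, DNA methylation and chromatin, imprinted, cancer-testis, HOX, Wnt signalling, glycolysis, immediate early and stress, heat shock and unfolded protein, and ribosomal proteins. Lists were tested with camera (limma, preset correlation 0.01, 1 probe per gene), adjusted over the 26 lists within a comparison, with an estimated correlation and with fry as alternatives. The p of fry asks whether the genes of a list move, on balance, one way, and compares them with no other genes. Of 132 list calls 38 held with an estimated correlation and 117 with fry. Where no count over the list alone is given, it equalled the count over all probes.

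Named genes are the 8 largest rises and falls (endoderm and EB-derived against hESC) or the 5 largest (other comparisons) past the threshold whose arrays did not overlap, so that every array of one group lay above every array of the other. The 10 largest differences of the interaction, 10 marker genes, and up to 4 members past the threshold and 2 not past it per list complete them, beside the genes found below the POU5F1 share in endoderm. Probes high in liver were those with an adjusted p under 0.05 and a log2 fold change of at least 2 against the hESCs of the line not tested.

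The fit and the list test were tried on simulated log2 values of 20550 probes. The floor, the log2 step and the normalization were not part of that test. Changed probes were drawn from those with a mean above the median, so detection of dimmer probes was not tested. For endoderm against hESC, 35 and 29 of 50 probes changed by -2 and 2 were called, 2 and 4 of 50 changed by -1 and 1, with 3 false calls. For the interaction 8 and 6 of 50 changed by -2 and 2 were called, 0 changed by -1 or 1, with 0 false calls. For liver against hESC 47 and 43 of 50, and 9 and 8 of 50, with 2 false calls. A list of 25 genes shifted by 1 was called in each of the 3 comparisons, and 0 of 25 lists without a shift. The simulated noise was independent between probes. False calls of lists whose genes vary together, such as immune (estimated correlation 0.49) and cell cycle genes (0.37), were therefore not tested.

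The alternatives fixed in advance were 1 or 50 added before log2, no further normalization, median centring, removal of dim probes (not above the array median in at least 2 arrays), no trend, the arrays of the groups compared alone, the replicate number as a block, and each array left out in turn. Where an array left out leaves a group with 1 array, that array is assumed to vary like the other groups. Quantile normalization before the floor, the EB effect from BG02 in the overlap with endoderm, and median centring for lists were added after the data were seen. No column of the table was left unused.

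For the test of scaling, each gene of the secreted hepatocyte and neural lists was replaced by 1 of the 50 probes in no list nearest to it in mean level over the hESC and EB-derived arrays, 1000 times under each scaling. An earlier test on the gap between the 2 list medians was dropped, since a shift of a whole array cannot change that gap. The bound of 10% for left-over cells was first set on 1 POU5F1 probe and then asked of both. Both changes were made after the results were seen.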

Results

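Gene expression was measured on 15 one-colour Illumina beadchips in 7 groups. H9 and BG02 are human embryonic stem cell (hESC) lines. Undifferentiated hESCs of each line (2 arrays each) carry labels saying that the cells were sorted on CXCR4, a chemokine receptor, without the side of the gate. H9 definitive endoderm (2 arrays) was made with activin A, a ligand of the Nodal pathway, and sorted with CXCR4. Embryoid body (EB) derived cells of H9 and of BG02 (2 arrays each) were grown as suspended aggregates and then plated, and the labels of the BG02 ones also name H9 as the starting cells. Normal adult liver (3 arrays) and HCT116, a colon carcinoma line (2 arrays), complete the set. The labels do not say whether replicates were separate cultures, so every p-value below measures only the spread between these arrays, which may be technical. The number of arrays limits the precision, with 8 residual degrees of freedom over all groups. The spread is pooled over the 7 groups, so the HCT116 arrays, the closest pair (r = 0.996), enter every SE. If they are technical repeats, SEs and p-values of comparisons without HCT116 can be too small.

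The deposited intensities were of similar scale on 14 arrays, with upper quartiles of 243 to 270. HCT116 replicate 2 lay lower, with an upper quartile of 130 and a median intensity of 11.2 against 42.2 in replicate 1. The share of probes below 0 ran from 0% in HCT116 replicate 1 to 40.2% in H9 EB replicate 1. Liver replicate 2 stood apart at both ends, with a lowest value of -172, a highest of 105392 and 6.68% of its signal in its 10 brightest probes. After normalization, Pearson's r across probes, which are not independent replicates, was 0.996 between the HCT116 arrays, 0.971 in H9 hESC, 0.992 in BG02 hESC, 0.988 in endoderm, 0.966 in H9 EB and 0.982 in BG02 EB, and 0.932 to 0.973 among the liver arrays. The hESC lines correlated at 0.963 with each other and the EB-derived groups at 0.955, as means over pairs of arrays. Single arrays did not all group by line. H9 hESC replicate 1 lay nearer to the BG02 hESC arrays (0.98 and 0.975) than to its own replicate (0.971). H9 EB replicate 1 lay as near to BG02 EB replicate 1 (0.967) as to its own replicate (0.966). Liver lay nearest to BG02 EB-derived cells (0.769), then H9 EB-derived cells (0.734), BG02 hESC (0.717), endoderm (0.711), HCT116 (0.7) and H9 hESC (0.692). The first 3 principal components held 44.9%, 21.4% and 14.8% of the variance.

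Marker genes followed the labels in most groups. POU5F1, the pluripotency factor OCT4, had a mean intensity of 6770 in H9 hESC and 2970 in BG02 hESC, 1350 in endoderm, and 3.32 and 6.53 in the H9 and BG02 EB-derived cells. NANOG and SOX2 read the same 3.32 in H9 EB, the level shared there by values set to 0. SOX17, a transcription factor of endoderm, read 3770 in endoderm and 2.4 and 31.1 in H9 and BG02 hESC. The liver protein ALB (albumin) read 15200 in liver, 9170 in BG02 EB, 774 in H9 EB and at most 16.2 in the other groups. AFP, the fetal albumin homologue, read 16000 in BG02 EB and 6570 in H9 EB against 316 in liver. COL1A1, a fibrillar collagen, read 11700 and 17400 in H9 and BG02 EB and 92.5 in liver. SOX2 stayed near the background in every group, from 3.32 to 50, hESCs included (11.3 and 9.46), so its probe says nothing about pluripotency here. CXCR4 read 5920 in endoderm and 62.7 in H9 hESC, a gene used to sort both and therefore no finding between them.

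**Figure D1:**
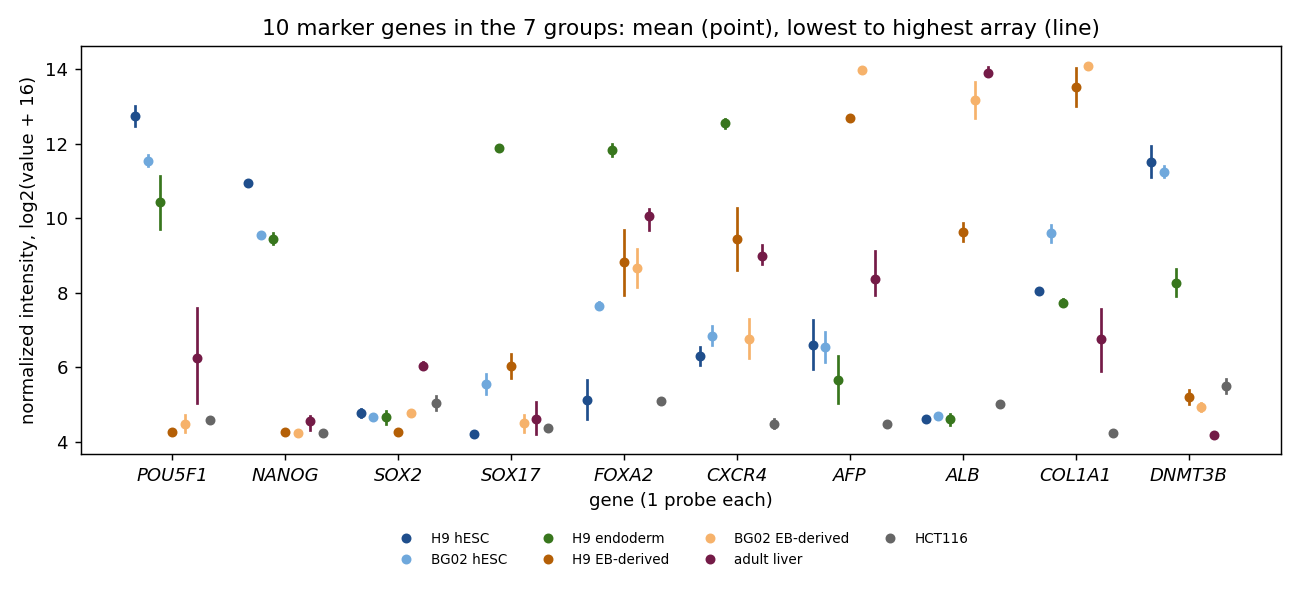
Level (y axis, log2 of normalized intensity plus 16) of 10 marker genes (x axis) in the 7 groups (colours), with points at the group mean and lines from the lowest to the highest array (2 arrays per group, 3 for liver). SOX17 stands highest in endoderm, AFP in the EB-derived cells, ALB in liver and BG02 EB, and POU5F1 in the hESC lines, with a mean intensity of 1350 left in endoderm.

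The first comparison asked what the activin A protocol changed in H9. Endoderm genes rose strongly: SOX17 by 7.69 on the log2 scale (SE 0.37, adjusted p = 1.8e-07, n = 2 against 2) and FOXA2, a pioneer factor of gut endoderm, by 6.7 (SE 0.51, adjusted p = 7.2e-06). The largest rise was in NPPB, a natriuretic peptide of heart muscle, at 8.29 (SE 0.53, adjusted p = 1.4e-06), followed by the growth factor FGF17 at 8.27 (SE 0.38), and the apolipoproteins APOA2 and APOA1 rose by 7.77 and 7.05. The cystatin gene CST1 (7.61), CCDC81 (7.13) and the collectin COLEC12 (7.09) completed the 8 largest. Among the 8 largest falls were MT1G, a metallothionein (-4.96, SE 0.81, adjusted p = 0.0019), TXNIP, an inhibitor of thioredoxin (-4.62, SE 0.35), the immediate early gene FOS (-4.61, SE 0.49), IDO1 (-4.69), CNMD (-4.61), THBS2 (-4.59), PTPRZ1 (-4.5) and USP44 (-4.21). In all, 1898 of 20550 probes changed (9.24%), 979 higher and 919 lower.

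By lists, definitive endoderm moved most in that comparison. Of its 21 measured genes 17 rose and none fell (20 rose when adjusted over the list alone), with a median of 3.2 (camera adjusted p = 9.9e-25, and 0.000407 with an estimated correlation). PRDM1 (6.43) and the Nodal antagonist CER1 (5.83) were among them, while FOXA3 (1.48) and CYP26A1 (2.55, with another probe past at 2.63) did not pass. Second probes of FOXA2 (0.30) and PRDM1 (0.35) did not pass. In the primitive streak list 7 of 15 genes rose (8 over the list alone), with EOMES at 6.99, GSC at 5.66 and LHX1 at 5.12. The median was 1.39 (adjusted p = 8.66e-09, and adjusted p = 0.126 with an estimated correlation). NODAL itself, at 1.39, did not pass (adjusted p = 0.069). Among the 11 Nodal target genes FST (3.26), LEFTY2 (2.81) and BAMBI (1.56) rose and SKIL fell by 1.85, and the list did not pass (adjusted p = 0.0688). Pluripotency genes fell in part. In that list 11 of 21 genes fell and 1 rose (14 and 1 over the list alone). The median was -1.53 (adjusted p = 4.36e-09, and adjusted p = 0.0906 with an estimated correlation). PRDM14 (-3.35), DNMT3B (-3.24, with a second probe at 0.45 that did not pass), CD24 (-3.02) and NANOG (-1.5, SE 0.27) fell, while LIN28A (-0.14) and SALL4 (-0.04) did not pass. POU5F1 fell too (-2.31, SE 0.64, adjusted p = 0.038, and -3.86 on a second probe). Its endoderm arrays differed from each other more (SD 1.01 on log2) than the hESC arrays (0.39).

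Genes of other germ layers moved in the endoderm arrays too. In the cardiac muscle list 5 of 18 genes rose, NPPB, the atrial light chains MYL4 (6.16) and MYL7 (5.87) and NPPA (3.06) among them, and MYH6 and ACTC1 did not pass. The median was 0.24 (adjusted p = 0.00313, and adjusted p = 0.373 with an estimated correlation). The mesenchyme and matrix list had 8 rises and 2 falls among 32 genes (9 and 2 over the list alone; adjusted p = 0.00495, and adjusted p = 0.456 with an estimated correlation), led by COL5A2 (4.03), and it was not called without endoderm replicate 2. In the visceral and yolk sac endoderm list APOA2, APOA1 and CUBN (1.47) rose among 17 genes, and the median stayed at 0.06 (adjusted p = 0.0182, and adjusted p = 0.33 with an estimated correlation). AFP, at -0.93, did not pass. Of 20 genes of Wnt signalling 5 rose and 1 fell (7 and 1 over the list alone; median 0.79, adjusted p = 0.00252, and adjusted p = 0.292 with an estimated correlation), with the inhibitors FRZB (4.93) and DKK1 (4.72) among the rises. Glycolysis genes fell in 7 of 19 cases and rose in 1 (median -0.97, adjusted p = 0.000556, and adjusted p = 0.33 with an estimated correlation), with PGAM1 at -3.3 and ALDOC at -2.3. Cell cycle genes fell in 7 of 32 cases and never rose (11 over the list alone; MCM3 -2.24; median -0.69, adjusted p = 4.05e-05, and adjusted p = 0.396 with an estimated correlation). The DNA methylation and chromatin list had 4 falls and 1 rise among 16 genes (5 and 1 over the list alone), with a median of -0.65 (adjusted p = 0.042, and adjusted p = 0.329 with an estimated correlation). That call ended without further normalization, with dim probes removed, and without H9 hESC replicate 2, endoderm replicate 2, liver replicate 2 or liver replicate 3.

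The remaining lists did not pass in endoderm against hESC. Among 31 secreted hepatocyte genes APOC1 (3.4) and HP (2.53) rose (median -0.06, mean 0.13, adjusted p = 0.65). Among 36 genes of hepatocyte metabolism CYP27A1 (2.28) and ASS1 (1.17, with a second probe at -0.66) rose (1 over the list alone; adjusted p = 0.416). None of 11 liver transcription factors changed (median -0.02, mean 0.11, adjusted p = 0.65). The trophoblast list held rises of HAND1 (5.52) and GATA3 (3.78) among 20 genes (2 rises and 1 fall over the list alone; adjusted p = 0.65). The neural ectoderm list had 3 rises and 1 fall among 26 (adjusted p = 0.101), with DLX5 at 3.8. TWIST1 (2.06) rose and 1 gene fell among 9 of neural crest (1 and 3 over the list alone; adjusted p = 0.771). VWF (4.92) rose among 20 endothelial and blood genes (adjusted p = 0.427), and CD74 (-2.43, with a second probe at -0.1) fell among 25 immune genes (0 over the list alone; adjusted p = 0.633). In the colon list 3 genes rose, KRT8 (3.54) and KRT19 (2.83) among them, and 1 fell (adjusted p = 0.178). Imprinted genes split 2 and 2 (3 and 2 over the list alone), with DLK1 at 3.56 (adjusted p = 0.101). Cancer-testis genes had 2 falls among 20 (3 over the list alone; median 0.02, mean -0.15, adjusted p = 0.646) and HOX genes 1 rise among 23, HOXB2 at 1.99 (adjusted p = 0.262). Among 14 immediate early genes FOS and EGR1 (-3.38) fell and 3 rose, with ATF3 at 1.95 (3 rises and 4 falls over the list alone; adjusted p = 0.633). The heat shock and unfolded protein list had 2 rises and 1 fall among 15 (4 and 1 over the list alone; adjusted p = 0.0688), and none of 31 ribosomal protein genes changed (adjusted p = 0.633).

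The endoderm count rested on few arrays. It fell to 767 without endoderm replicate 1, 1192 without endoderm replicate 2 and 1020 without H9 hESC replicate 2, and to 635 with the spread taken from the H9 hESC and endoderm arrays alone. Without further normalization 65.7% of the changed probes were higher (882 against 461), against 51.6% here, and with median centring 47.6% (798 against 879). The median of all probes was 0.38 in the first setting and 0.19 in the second. POU5F1 lost its call without any single array of HCT116, H9 hESC, BG02 hESC or BG02 EB, without endoderm replicate 1 or liver replicate 3, and with 1 added before log2, no trend or normalization before the floor. NANOG lost its call with 1 added or without further normalization, and PTPRZ1 without endoderm replicate 1. BAMBI and SKIL lost theirs with median centring and without H9 hESC replicate 2 or endoderm replicate 1. SKIL also lost its call without endoderm replicate 2 or any single array of HCT116, BG02 hESC or BG02 EB, and with 1 added, no further normalization or normalization before the floor. With the spread from the H9 hESC and endoderm arrays alone POU5F1, PTPRZ1, BAMBI and SKIL did not pass.

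EB differentiation of H9, the second comparison, brought up connective tissue genes. The small proteoglycans DCN and LUM rose by 9.76 (SE 0.34, adjusted p = 8.4e-09, n = 2 against 2) and 9.57 (SE 0.78), the collagen COL3A1 by 9.09 (SE 0.29, adjusted p = 5.5e-09) and the matrix protein MGP by 8.07. HAND1, a factor of heart and extraembryonic mesoderm, rose by 9.21 (SE 0.55), the water channel AQP1 by 8.53, and the imprinted growth regulators DLK1 and IGF2 by 7.5 and 7.39. Pluripotency genes led the falls, with the Nodal antagonist LEFTY1 at -8.98 (SE 0.4), POU5F1 at -8.46 (SE 0.64, adjusted p = 3.8e-06), ZSCAN10 at -8.04 (SE 0.23), L1TD1 at -7.26, NANOG at -6.68 (SE 0.27), DNMT3B at -6.31 (a second probe at -0.07 did not pass), USP44 at -6.06 and SCGB3A2 at -5.66. In all, 4023 probes changed (19.6%), 1889 higher and 2134 lower, and 1987 and 1986 with median centring.

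In H9 EB-derived cells 27 of 32 mesenchyme and matrix genes rose (28 rose and 1 fell over the list alone; median 3.84, adjusted p = 3e-23, and 0.0213 with an estimated correlation), and 19 of 21 pluripotency genes fell (median -3.53, adjusted p = 5.71e-21, and 0.0117 with an estimated correlation). Visceral and yolk sac endoderm genes rose in 14 of 17 cases (median 2.98, adjusted p = 1.88e-14, and 0.0117 with an estimated correlation), among them APOA1 (7.13), TTR (6.92) and AFP (6.08). HOX genes rose in 14 of 23 (median 2.43, adjusted p = 1.88e-14, and 0.0213 with an estimated correlation), with HOXB5 at 6.74 and HOXB8 at 5.77. These 4 lists held with an estimated correlation and the other 11 called ones did not. Cardiac genes rose in 11 of 18 (MYH6, the atrial myosin heavy chain, by 6.66; median 1.77, adjusted p = 2.72e-07, and adjusted p = 0.107 with an estimated correlation). Neural ectoderm genes rose in 11 of 26 and fell in 2 (12 and 2 over the list alone; median 1.32, adjusted p = 2.18e-06, and adjusted p = 0.126 with an estimated correlation), with the Notch target HES5 at 5.72, LHX2 at 5.32 and the microtubule protein DCX at 3.88 (a second DCX probe, at -0.15, did not pass). Secreted hepatocyte genes rose in 9 of 31 (AHSG 5.31, ALB 5.02; median 0.32, adjusted p = 0.000268, and adjusted p = 0.285 with an estimated correlation). Cell cycle genes fell in 12 of 32 (13 over the list alone), with BUB1 at -3.16 and MCM6 at -2.44. The median was -0.93 (adjusted p = 6.69e-06, and adjusted p = 0.28 with an estimated correlation). The 2 H9 EB arrays lay apart in this list (mean log2 level 8.81, SD 0.69), against 9.9 (SD 0.073) in H9 hESC.

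A further 7 lists were called in the H9 EB comparison. Definitive endoderm had 9 rises and 2 falls (10 and 2 over the list alone; STMN2 7.26, FOXA1 3.97; adjusted p = 0.00336, and adjusted p = 0.101 with an estimated correlation). Trophoblast had 6 and 1 (7 and 1 over the list alone; TFAP2A 4.72; adjusted p = 0.0036, and adjusted p = 0.142 with an estimated correlation). Wnt signalling had 9 and 3 (FRZB 6.92, DKK1 6.69; adjusted p = 0.00123, and adjusted p = 0.107 with an estimated correlation). Chromatin genes had 1 and 6 (HELLS -3.37, TET1 -2.84; adjusted p = 0.00362, and adjusted p = 0.107 with an estimated correlation) and imprinted genes 6 and 2 (PLAGL1 4.22; adjusted p = 0.0102, and adjusted p = 0.0864 with an estimated correlation). Nodal targets had 1 rise and 4 falls (adjusted p = 0.0278, and adjusted p = 0.126 with an estimated correlation), a call lost without H9 hESC replicate 2, H9 EB replicate 2 or liver replicate 2. The endothelial and blood list had 4 rises and 1 fall (TEK 4.23; adjusted p = 0.0408, and adjusted p = 0.107 with an estimated correlation), lost with 50 added and without either H9 hESC array or H9 EB replicate 2. With the spread taken from the H9 hESC and EB arrays alone 748 probes passed.

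The same comparison in BG02 had liver genes among its largest rises, beside the connective tissue ones, while in H9 liver genes such as ALB rose less (5.02). LUM rose by 9.8 (SE 0.78), MGP by 9.39, DCN by 9.25 (SE 0.34), HAND1 by 9.07, COL3A1 by 8.8 and IGF2 by 8.5. SERPINA3, a protease inhibitor secreted by hepatocytes, rose by 8.92 (SE 0.63, adjusted p = 1.8e-06, n = 2 against 2) and ALB by 8.48 (SE 0.29, adjusted p = 8e-09). The falls were led by ZSCAN10 (-7.56, SE 0.23), POU5F1 (-7.05, SE 0.64, adjusted p = 1.4e-05), DNMT3B (-6.32, with a second probe at -0.34 that did not pass), L1TD1 (-6.3), GLIPR1L1 (-5.83), CFAP95 (-5.73), LEFTY2 (-5.55) and NODAL (-5.52). In all, 3814 probes changed (18.6%), 1860 higher and 1954 lower. That balance turned to 1700 and 1350 without further normalization and to 1488 and 1423 with 50 added, against 1706 and 2142 with median centring.

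In BG02 EB-derived cells 29 of 32 mesenchyme genes rose (median 3.36, adjusted p = 5.72e-27, and 0.0183 with an estimated correlation). So did 15 of 17 visceral and yolk sac endoderm genes (VTN 7.84, FGB 7.55, AFP 7.42; median 4.94, adjusted p = 3.2e-19, and 0.00838). Pluripotency genes fell in 18 of 21 cases (median -3.71, adjusted p = 4.76e-19, and 0.01). Those were the 3 lists that held with an estimated correlation. Secreted hepatocyte genes rose in 20 of 31 (AHSG 7.7, AMBP 6.87; median 2.52, adjusted p = 4.5e-17, and adjusted p = 0.0751 with an estimated correlation). Metabolic hepatocyte genes rose in 11 of 36 (12 over the list alone; NNMT 6.1, ADH1A 5; adjusted p = 1.31e-05, and adjusted p = 0.207 with an estimated correlation). Only CEBPB (1.17) rose among 11 liver transcription factors (0 over the list alone), and that list did not pass (adjusted p = 0.0915). Cell cycle genes fell in 25 of 32 (29 over the list alone; CCNA2 -2.45; median -1.62, adjusted p = 2.56e-12, and adjusted p = 0.113 with an estimated correlation). Cardiac genes rose in 11 of 18 (MYH6 8.35, NPPA 7.86; adjusted p = 4.33e-10, and adjusted p = 0.0759 with an estimated correlation) and HOX genes in 11 of 23 (12 over the list alone; HOXB5 6.02; adjusted p = 1.05e-07, and adjusted p = 0.0759 with an estimated correlation). Neural ectoderm genes split 3 and 5, with ZEB2 at 3.44 and ZIC2 at -4.19 (median -0.05, adjusted p = 0.598). Definitive endoderm genes split 6 and 3 (7 and 4 over the list alone; median 0.49, adjusted p = 0.0238, and adjusted p = 0.129 with an estimated correlation), and that call was lost without BG02 EB replicate 2. Trophoblast (9 rose, 1 fell), Wnt signalling (8 and 3), colon (6 and 0, and 6 and 1 over the list alone), imprinted (4 and 1, and 5 and 2 over the list alone), chromatin (1 and 6) and primitive streak genes (1 and 7) were called too, with adjusted p from 0.000275 to 0.0138. None of these 6 held with an estimated correlation (adjusted p = 0.0759 to 0.3). The count of probes was 2467 without BG02 hESC replicate 1, 2470 without BG02 hESC replicate 2 and 2507 without BG02 EB replicate 1.

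Over both lines the EB effects ran together. Their Pearson r across probes was 0.804 (Spearman rho 0.677), with 1217 probes higher in both (171 for independent sets), 1143 lower in both (203) and 6 opposite, from comparisons that share no arrays. The mean effect changed 4273 probes, 2045 higher and 2228 lower (1497 and 1440 with 50 added), led by LUM (9.68, SE 0.55), DCN (9.51, SE 0.24), HAND1 (9.14), COL3A1 (8.95) and MGP (8.73), and by ZSCAN10 (-7.8, SE 0.16), POU5F1 (-7.75), LEFTY1 (-7.13), L1TD1 (-6.78) and DNMT3B (-6.32). Of 26 lists 17 were called and 4 held with an estimated correlation, namely pluripotency (0 rose, 19 fell), visceral and yolk sac endoderm (14 rose, 0 fell), mesenchyme (28 rose, 0 fell) and HOX (12 rose, 0 fell).

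**Figure D2:**
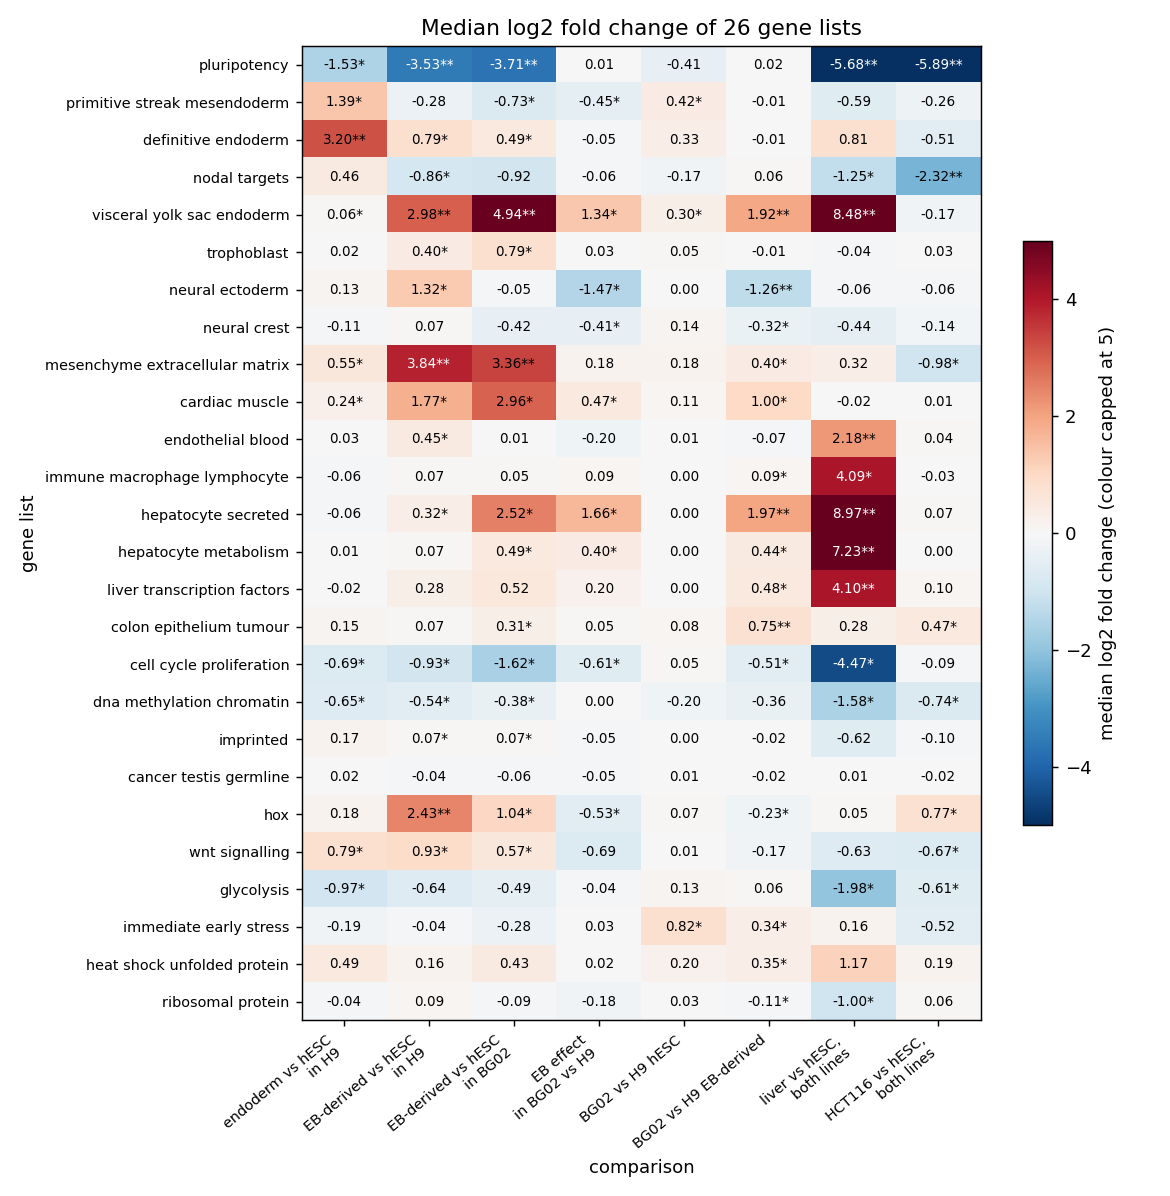
Median log2 fold change of 26 gene lists (vertical axis) in 8 comparisons (horizontal axis), given as a number and as colour, which stops at 5. One star marks a camera adjusted p under 0.05 and 2 stars one that also held with an estimated correlation, as for definitive endoderm in the endoderm arrays (median 3.2).

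The EB effect was then compared between the lines by an interaction term. Several liver genes rose more in BG02 and several neural genes more in H9. SERPINA3 differed by 5.04 (SE 0.89, adjusted p = 0.021, n = 2 per group) and IGFL2 by 4.41 (SE 0.6), both higher in the BG02 effect. HES5 differed by -7.4 (SE 0.78, adjusted p = 0.00089), reading 1300 in H9 EB against 26.6 in BG02 EB, while its hESC levels were 8.93 and 120. FABP7, a fatty acid binding protein of radial glia (-4.59, SE 0.73), DCX (-4.58, SE 0.51, with a second probe at 0.45 that did not pass), TAGLN3 (-4.38) and the hindbrain gene HOXA2 (-4.24) went the same way, as did RHBDL3 (-4.78), TLCD3B (-4.59) and CST1 (-4.72). In all, 157 probes differed (0.764%), 66 higher and 91 lower in the BG02 effect, and 81 and 76 without further normalization.

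Among lists, secreted hepatocyte genes had 9 higher and 0 lower in the BG02 effect (17 and 0 over the list alone; KNG1 3.95, HP 3.87; median 1.66, adjusted p = 1.24e-19, and adjusted p = 0.114 with an estimated correlation). Neural ectoderm had 0 higher and 5 lower, HES5, FABP7 and DCX among them (0 and 9 over the list alone; median -1.47, adjusted p = 2.44e-13, and adjusted p = 0.114 with an estimated correlation). Visceral and yolk sac endoderm had 4 and 1 (7 and 3 over the list alone; APOC3 4.04; median 1.34, adjusted p = 0.000626, and adjusted p = 0.209 with an estimated correlation), with AFP, at 1.34, not past the threshold. HOX had 0 and 2 (0 and 4 over the list alone; median -0.53, adjusted p = 4.16e-05, and adjusted p = 0.209 with an estimated correlation), and neural crest 0 and 1 (0 and 3 over the list alone; median -0.41, adjusted p = 0.00626, and adjusted p = 0.181 with an estimated correlation), a call lost without H9 hESC replicate 1. Of 9 lists called by camera these 5 also passed fry and none held with an estimated correlation. Metabolic hepatocyte genes (median 0.4), cardiac genes (0.47), cell cycle genes (-0.61) and primitive streak genes (-0.45) were the other 4, with no single gene past the threshold. Over the list alone 1 metabolic and 1 cardiac gene were higher and 2 primitive streak genes lower.

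The interaction count moved with single arrays. It was 808 without H9 hESC replicate 1, 67 without H9 hESC replicate 2, 349 without H9 EB replicate 1, 72 and 54 without BG02 hESC replicate 1 and 2, 104 without BG02 EB replicate 2, 103 and 104 without HCT116 replicate 1 and 2, and 254 without liver replicate 2. It was 36 with the spread from the 8 hESC and EB arrays alone, where SERPINA3, CST1, FABP7, IGFL2, TAGLN3 and HOXA2 lost their calls. SERPINA3 also lost its call without H9 hESC replicate 2, either BG02 hESC array or BG02 EB replicate 2, FABP7 without H9 hESC replicate 2 or BG02 hESC replicate 2, and TAGLN3 without BG02 hESC replicate 2. FABP7, DCX and HOXA2 lost theirs with 1 added before log2.

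**Figure D3:**
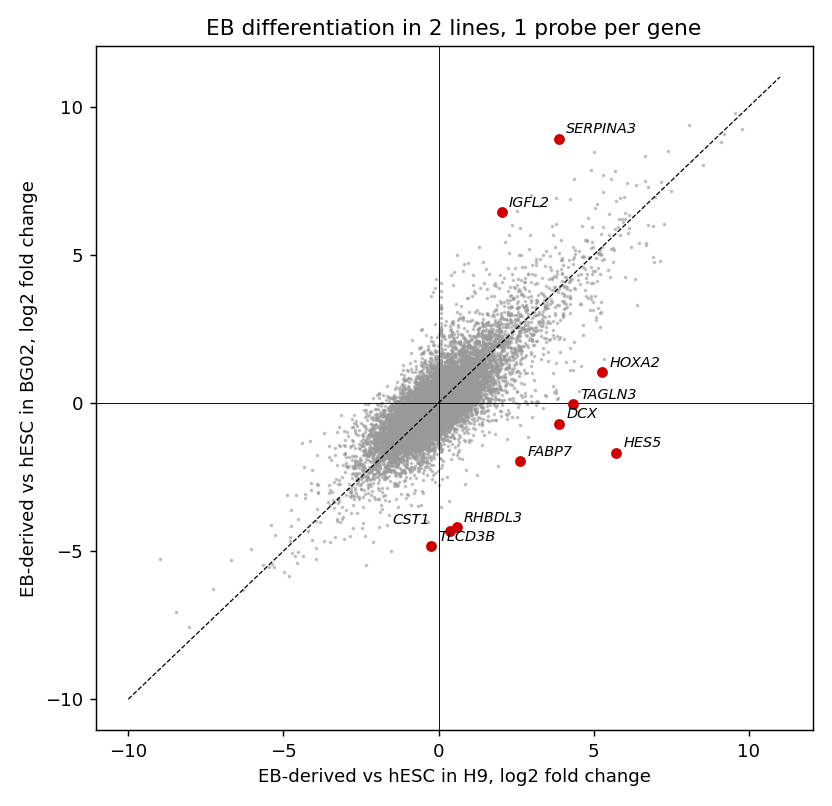
Log2 fold change of EB-derived cells against hESC in H9 (x axis) and in BG02 (y axis), 1 point per gene, with equal effects on the dashed line and the 10 genes with the largest tested difference in red. Most genes follow the line (r = 0.804 over all probes), while HES5 lies far below it and SERPINA3 above it.

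Endoderm and EB-derived H9 cells, directed against undirected differentiation, differed in single genes by up to 10 on the log2 scale. LEFTY1 was higher in endoderm by 10 (SE 0.4, adjusted p = 4.3e-08, n = 2 against 2), FGF17 by 8.7, CER1 by 8.67, the T-box factor EOMES by 8.66 (SE 0.64) and LEFTY2 by 8.28. DCN was lower at -9.17 (SE 0.34), as were AQP1 (-8.52), COL3A1 (-8.43), MGP (-8.12) and MYH6 (-7.3). In all, 2529 probes differed (12.3%), 1241 higher and 1288 lower in endoderm, a balance that turned without further normalization (1173 and 942) and with 1 added (1371 and 1304). The pluripotency list had 13 genes higher and 0 lower in endoderm (median 1.92, adjusted p = 1.59e-13, and 0.02 with an estimated correlation). Definitive endoderm had 15 and 1 (17 and 2 over the list alone; median 2.23, adjusted p = 9.14e-10, and 0.0136) and Nodal targets 5 and 1 (6 and 1 over the list alone; adjusted p = 0.000689, and 0.0446). HOX genes had 0 and 15 (median -2.42, adjusted p = 6.43e-16, and 0.02), mesenchyme 0 and 22 (0 and 24 over the list alone; median -2.79, adjusted p = 4.47e-22, and 0.0233) and visceral endoderm 2 and 11 (AFP -7.01, TTR -6.85; median -2.7, adjusted p = 9e-09, and 0.0233). These 6 lists held with an estimated correlation. Primitive streak genes were higher in 8 of 15 and lower in 1 (median 2.64, adjusted p = 2.05e-07, and adjusted p = 0.0783 with an estimated correlation), and secreted hepatocyte genes 2 and 9 (2 and 10 over the list alone; adjusted p = 0.000432, and adjusted p = 0.324 with an estimated correlation). Imprinted (0 and 3, adjusted p = 0.011), trophoblast (1 and 6, 1 and 7 over the list alone, adjusted p = 0.00195), neural ectoderm (2 and 10, adjusted p = 0.000539), cardiac (1 and 5, 1 and 7 over the list alone, adjusted p = 0.00664) and neural crest genes (0 and 3, 0 and 4 over the list alone, adjusted p = 0.0432) were called as well, with adjusted p = 0.0616, 0.167, 0.279, 0.324 and 0.179 with an estimated correlation. The neural and cardiac calls ended without H9 EB replicate 2, and that of neural crest with 50 added and without either H9 hESC array, endoderm replicate 1, BG02 EB replicate 1 or liver replicate 1 or 2. Without endoderm replicate 1 or 2 the count was 1409 or 1657, with the spread from the 4 arrays compared 1077, and the median of all probes shifted by 0.49 without further normalization.

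Both H9 differentiations were set against the same hESC arrays, and shared controls alone can make their effects correlate. Higher in both were 488 probes (90 for independent sets) and lower in both 599 (95.4), with 53 opposite. In 100 simulations of unchanged groups against those controls the overlap of calls was 0, as such groups give hardly any calls, so that value leaves out the effects and the counts for independent sets leave out the shared controls. Part of the excess over either may come from the shared controls. Pearson's r was 0.522 (rho 0.537) against a simulated mean of 0.5 and a highest of 0.525, while the covariance was 0.467 against 0.0598, a difference of 0.407. With the EB effect taken from BG02, which shares no array, 386 probes were higher in both (88.6 for independent sets) and 461 lower in both (87.4), r was 0.393 and 76 were opposite. The H9 overlap, 1087 probes in all, was 1719 without H9 hESC replicate 1, 535 without H9 hESC replicate 2, 449 without endoderm replicate 1, 672 without endoderm replicate 2 and 709 without further normalization.

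Undifferentiated BG02 and H9 cells differed in few genes. CHCHD2, a mitochondrial protein, was lower in BG02 at -7.39 (SE 0.22, adjusted p = 5.8e-09, n = 2 against 2), as were SMC6 (-4.14, SE 0.47), the DNA repair gene MGMT (-3.27, SE 0.49, adjusted p = 0.0065), ARHGAP28 (-3.12) and GANAB (-3.11). CST1 was higher by 5.18 (SE 0.43), APOA1 by 4.26 (SE 0.33), DNAJC15 by 4.01 (SE 0.25, adjusted p = 1.2e-05), QPCT by 3.79 (SE 0.59) and ZNF280D by 3.79 (SE 0.33). CST1, APOA1 and APOA2 were among the largest rises of H9 endoderm as well. In the definitive endoderm list FOXA2 (2.52, adjusted p = 0.029, reading 185 against 19.1) and FLRT3 (1.51) were higher in BG02, second probes of both (-0.07 and -0.2) did not pass, and neither did the list (2 of 21 higher, 3 over the list alone; median 0.33, adjusted p = 0.18). NANOG was lower at -1.39 (adjusted p = 0.024), the only 1 of 21 pluripotency genes past the threshold, and the list did not pass (adjusted p = 0.158). In all, 348 probes differed (1.69%), 209 higher and 139 lower. The visceral endoderm list (APOA1 and, at 3.04, APOA2; adjusted p = 0.0119), the primitive streak list (CDX1 1.47, 4 genes over the list alone; adjusted p = 0.039) and the immediate early list (none past; adjusted p = 0.039) were called, each with adjusted p = 0.766 with an estimated correlation and not by fry. All 3 calls ended with 50 added, and those of the primitive streak and immediate early lists without H9 hESC replicate 2 or BG02 hESC replicate 2, the first also without either H9 EB array or liver replicate 1.

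With single arrays left out, that count moved more than any other. It was 1820 without H9 hESC replicate 1, 58 without H9 hESC replicate 2, 88 and 47 without BG02 hESC replicate 1 and 2, 162 and 156 without HCT116 replicate 1 and 2, 230 and 216 without BG02 EB replicate 1 and 2, and 546 without liver replicate 2. It was 182 without further normalization, 190 with median centring and 2 with the spread from the 4 arrays alone. CHCHD2 and CST1 alone of the 10 most different genes kept their calls in that last setting. NANOG lost its call there, without H9 hESC replicate 2, either BG02 hESC array or either HCT116 array, and under other scalings, FOXA2 there, without any single array of HCT116, endoderm or BG02 hESC or H9 hESC replicate 2, with 50 added and with normalization before the floor, FLRT3 there, without either BG02 hESC array or H9 hESC replicate 2 and with 50 added, QPCT without H9 hESC replicate 2 or BG02 hESC replicate 2, MGMT without BG02 hESC replicate 2 and ARHGAP28 without H9 hESC replicate 2.

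After EB differentiation the lines differed in 15 of the 26 lists, 4 of which held with an estimated correlation. SERPINA5 (5.27, SE 0.71, adjusted p = 0.0013, n = 2 against 2), DYNLT3 (5.03, SE 0.32), SERPINA3 (4.8, SE 0.63), GPX2 (4.51) and the alcohol dehydrogenase ADH1A (4.42) were higher in BG02, and CHCHD2 (-8.88, SE 0.22, adjusted p = 6.4e-10), HES5 (-4.95, SE 0.55), MGMT (-4.65, SE 0.49), TLCD3B (-4.39) and RHBDL3 (-4.2) lower. In all, 531 probes differed (2.58%), 309 higher and 222 lower. Secreted hepatocyte genes were higher in 18 of 31 cases (20 over the list alone; median 1.97, adjusted p = 6.74e-29, and 0.0326 with an estimated correlation). So were visceral endoderm genes in 10 of 17 (12 higher and 1 lower over the list alone; median 1.92, adjusted p = 6.04e-16, and 0.0158) and colon genes in 2 of 22 (6 over the list alone; median 0.75, adjusted p = 9.05e-06, and 0.0439). Neural ectoderm genes were lower in 8 of 26 (12 over the list alone; ZIC2 -4.09, DCX -3.95 with a second probe at 0.4 that did not pass; median -1.26, adjusted p = 1.25e-15, and 0.0439). Metabolic hepatocyte genes were higher in 6 of 36 (9 over the list alone; adjusted p = 3.61e-08, and adjusted p = 0.174 with an estimated correlation) and HOX genes lower in 4 of 23 (6 over the list alone; adjusted p = 1.11e-05, and adjusted p = 0.141 with an estimated correlation). Cardiac genes were higher in 3 of 18 (8 higher and 1 lower over the list alone; adjusted p = 1.76e-07, and adjusted p = 0.14 with an estimated correlation). Neural crest genes were lower in 1 of 9 (3 over the list alone; median -0.32, adjusted p = 0.00707, and adjusted p = 0.127 with an estimated correlation) and immune genes higher in 3 of 25 (4 over the list alone; median 0.09, adjusted p = 0.0252, and adjusted p = 0.661 with an estimated correlation). With no single gene past the threshold, the cell cycle (median -0.51, adjusted p = 2.68e-06) and ribosomal protein lists (-0.11, adjusted p = 0.0167) were called lower. Liver transcription factors (0.48, adjusted p = 0.0174), immediate early (0.34, adjusted p = 0.0264) and heat shock genes (0.35, adjusted p = 0.0405) were called higher in the same way. None of these 5 passed fry or an estimated correlation (adjusted p = 0.319 to 0.515), and each call ended without H9 EB replicate 2. Without BG02 EB replicate 2 the ribosomal, liver transcription factor, immediate early and heat shock calls ended too. The immune call ended without H9 EB replicate 1 or BG02 EB replicate 1 and with 50 added, and did not pass fry. With 50 added the liver transcription factor call ended, with median centring and with dim probes removed those of immediate early and heat shock genes, and without further normalization or BG02 EB replicate 1 that of heat shock genes. SERPINA3 itself varied more in H9 EB (log2 level 8.32, SD 1.96) than in BG02 EB (13.12, SD 0.76). The count was 840 without H9 EB replicate 1, 267 without BG02 EB replicate 2 and 1 with the spread from the 4 arrays compared, where CHCHD2 alone of the 10 genes kept its call. The mesenchyme list, called at a median of 0.4 (adjusted p = 0.00911, and adjusted p = 0.462 with an estimated correlation) with no single gene past, turned to -0.14 without H9 EB replicate 2 and was not called without BG02 EB replicate 1, without further normalization or with median centring.

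Line differences carried over. Across the 348 probes that differed between the hESC lines, the differences correlated with those between the EB-derived cells at r = 0.623, 78.7% had the same sign (274) and 57 passed there too with the same sign, against 1 with the opposite. Permuting the probes 10000 times gave r from -0.197 to 0.2 and a share of the same sign of 49.1% on average and 57.8% at most. The correlation was 0.429 without H9 hESC replicate 1, 0.773 without H9 hESC replicate 2 and 0.751 and 0.75 without BG02 hESC replicate 1 and 2.

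**Figure D4:**
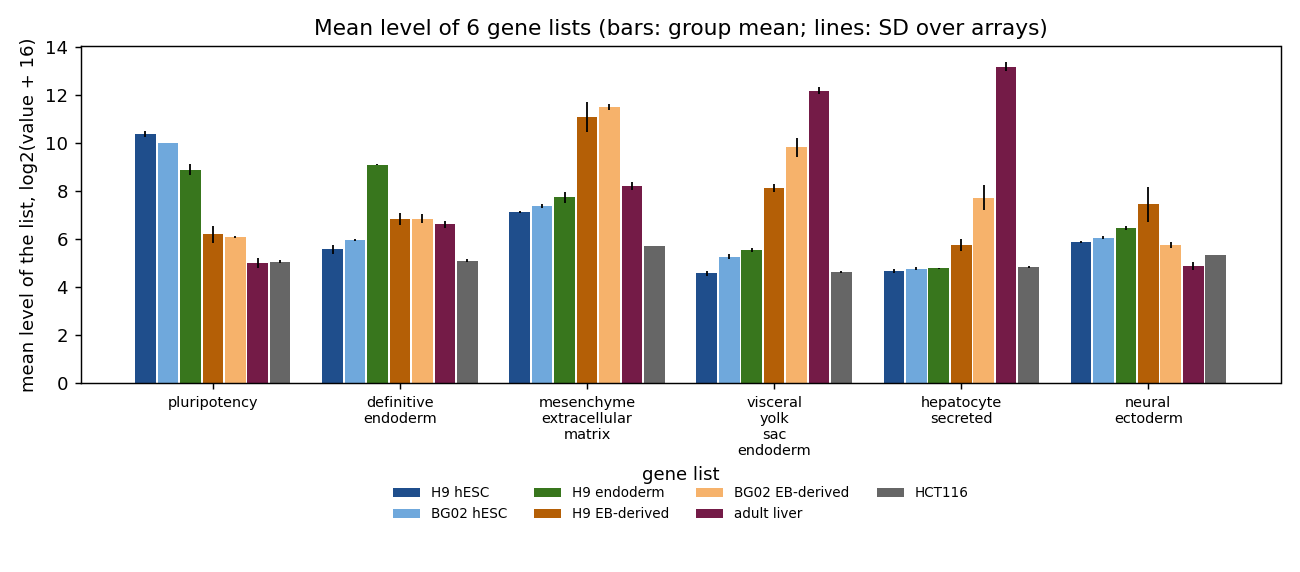
Mean level (y axis, log2 of normalized intensity plus 16, from 0) of the genes of 6 lists (x axis) in the 7 groups (colours), with bars at the mean over arrays and lines for the SD over arrays (2 arrays per group, 3 for liver). Secreted hepatocyte genes stand at 7.74 in BG02 EB against 5.75 in H9 EB and 13.2 in liver, and neural genes at 7.45 in H9 EB against 5.77 in BG02 EB.

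Adult liver, measured as the mature tissue, differed from hESCs in 6870 probes (33.4%), 2952 higher and 3918 lower. SERPINA3 (9.99, SE 0.48, adjusted p = 5.2e-09, n = 3 against 4), the fibrinogen-like FGL1 (9.88), complement factor CFB (9.88, SE 0.23, adjusted p = 2.3e-11), the heme carrier HPX (9.83) and SAA4 (9.83) rose most. LIN28A, an RNA-binding pluripotency factor (-8.76, SE 0.46), DPPA4 (-8.44), TUBB2B (-8.2), LEFTY1 (-8.07) and ZSCAN10 (-7.93) fell most. Among 31 secreted hepatocyte genes 30 rose (F12, at 2.21, did not pass; median 8.97, adjusted p = 6.6e-28, and 0.016 with an estimated correlation). Metabolic genes rose in 35 of 36 cases (CYP2E1 9.7; CYP7A1, at 0.07, did not pass; median 7.23, adjusted p = 1.01e-26, and 0.016). Liver transcription factors rose in 10 of 11 (CREB3L3 7.08; median 4.1, adjusted p = 4.9e-08, and 0.0212) and visceral endoderm genes in 16 of 17 (median 8.48, adjusted p = 6.11e-15, and 0.0114). Markers of other liver cells were high beside them. Endothelial and blood genes rose in 13 of 20 (HBB 9.27, CDH5 4.43; median 2.18, adjusted p = 6.88e-06, and 0.0114) and immune genes in 21 of 25 (C1QA 7.98, CD14 7.93; median 4.09, adjusted p = 1.69e-12, and adjusted p = 0.137 with an estimated correlation). All 32 cell cycle genes fell (CCNB2 -6.48, BUB1B -6.41; median -4.47, adjusted p = 1.7e-17, and adjusted p = 0.0639 with an estimated correlation). In the pluripotency list 19 of 21 genes fell and SOX2, near the background in both, read higher (1.32; median -5.68, adjusted p = 1.57e-12, and 0.016 with an estimated correlation). Glycolysis genes fell in 12 of 19 (adjusted p = 0.00123, and adjusted p = 0.295 with an estimated correlation). Nodal targets fell in 7 of 11 and rose in 0 (7 and 1 over the list alone; adjusted p = 0.00267), and chromatin genes fell in 10 of 16 and rose in 2 (UHRF1 -5.17; adjusted p = 0.000921), both with adjusted p = 0.0639 with an estimated correlation. Ribosomal protein genes fell in 16 of 31 (median -1, adjusted p = 1.63e-06, and adjusted p = 0.214 with an estimated correlation), a call lost without further normalization and with median centring. Without further normalization 54.9% of changed probes were higher (4107 against 3376), against 43% here, with a shift of 0.21 in the median of all probes.

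Set against H9 endoderm, liver differed in 6321 probes (30.8%), 2693 higher and 3628 lower. SERPINA3 (10.09, SE 0.58), CFB (10.08, SE 0.27, adjusted p = 1.7e-10, n = 3 against 2), the acid glycoproteins ORM1 (9.99) and ORM2 (9.9) and FGL1 (9.93) were higher in liver, and LEFTY1 (-9.82, SE 0.37, adjusted p = 1.2e-09), NPPB (-9.42), LEFTY2 (-9.4), CST1 (-9.26) and LIN28A (-8.82) lower. Definitive endoderm genes were lower in 14 of 21 cases (CER1 -8.68, SOX17 -7.27; median -1.79, adjusted p = 2.79e-05, and 0.0182 with an estimated correlation) and higher in 1. Secreted hepatocyte genes were higher in 30 of 31 (median 8.91, adjusted p = 7.83e-31, and 0.0143), metabolic genes in 35 of 36 (median 7.3, adjusted p = 5.14e-29, and 0.0143), and liver transcription factors in 10 of 11 (median 3.83, adjusted p = 1.82e-08, and 0.0182). Immune genes were higher in 21 of 25 (adjusted p = 4.01e-14, and adjusted p = 0.0953 with an estimated correlation) and cell cycle genes lower in 31 of 32 (median -3.57, adjusted p = 2.45e-15, and adjusted p = 0.0768 with an estimated correlation). In all, 15 lists were called and 8 held with an estimated correlation. Median centring moved the median of all probes by -0.29, and the fall of ribosomal protein genes, 14 of 31 (adjusted p = 4.27e-06, and adjusted p = 0.193 with an estimated correlation), was lost with it and without further normalization.

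Probes high in liver were then followed into the differentiated cells, with the set taken from liver against the hESCs of the other line. In H9 endoderm 159 of 1603 such probes rose and 46 fell (9.92% rose against 4.33% of other probes; median 0.044, camera p = 0.0022, and p = 0.07 with an estimated correlation). In H9 EB-derived cells 444 rose and 55 fell (27.7% against 7.63%; median 0.234, camera p = 4.1e-11, and p = 0.002 with an estimated correlation). In BG02 EB-derived cells 593 of 1699 rose and 42 fell (34.9% against 6.72%; median 0.629, camera p = 3.7e-21, and p = 0.00034 with an estimated correlation). These medians moved with the scaling and with single arrays, while each call at the preset correlation stayed. In endoderm the median was 0.537 without further normalization, 0.345 with median centring and 0.021 with 50 added. In H9 EB-derived cells it was 0.064, 0.143 and 0.151 in the same settings, 0.365 with normalization before the floor, and 0.065 and 0.151 without H9 EB replicate 1 and 2. The endoderm median thus stood above the H9 EB one without further normalization and with median centring, and the order of these 2 medians rests on quantile normalization. Endothelial and blood genes rose in liver too (13 of 20), so these sets are not of hepatocytes alone. The sets were also chosen to be lower in hESCs than in liver, and the 2 hESC lines correlated at 0.963. Such probes have more room to rise than to fall in any differentiated cell. No set matched in hESC level was tested, so part of the excess of rises may come from the choice of the set.

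HCT116 differed from the hESC lines in 5545 probes, 2805 higher and 2740 lower, a balance that hung on the scaling (3599 and 2677 with median centring, 2429 and 2959 without further normalization). ADIRF (8.48, SE 0.36, adjusted p = 8.4e-09, n = 2 against 4), the embryonic globin HBE1 (8.13, SE 0.57), the Wnt inhibitor DKK1 (7.9, SE 0.39), the cancer-testis antigen MAGEB2 (6.95) and GTSF1 (6.79) rose most, and TUBB2B (-9.73, SE 0.29), DPPA4 (-8.97, SE 0.28, adjusted p = 7e-10), SNURF (-8.86), LIN28A (-8.75) and SNRPN (-8.68, with other probes at -6.64 and, not past, at -0.06) fell most. Pluripotency genes fell in 19 of 21 cases (median -5.89, adjusted p = 1.28e-17, and 0.0238 with an estimated correlation) and Nodal targets in 8 of 11 (LEFTY1 -8.23, FST -5.02; median -2.32, adjusted p = 9.29e-06, and 0.026). HOX genes rose in 11 of 23 (HOXB7 6.77, HOXB8 5.8; median 0.77, adjusted p = 0.000443, and adjusted p = 0.382 with an estimated correlation). Mesenchyme genes fell in 16 of 32 and rose in 2 (THY1 -7.21, COL5A2 -4.95; median -0.98, adjusted p = 0.000156), Wnt genes fell in 9 of 20 and rose in 1 (adjusted p = 0.00701) and glycolysis genes fell in 6 of 19 (SLC2A3 -6.94; adjusted p = 0.00439), each with adjusted p = 0.382 with an estimated correlation.

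The colon list itself passed narrowly in HCT116, with 7 of 22 genes higher and 2 lower (EREG 4.37, CDX2 3.61, KRT20 2.5; median 0.47, adjusted p = 0.0499, and adjusted p = 0.382 with an estimated correlation), as did the chromatin list in the other direction (3 higher, 6 lower; JARID2 -4.85; median -0.74, adjusted p = 0.0499, and adjusted p = 0.382 with an estimated correlation). Both calls ended without HCT116 replicate 1, H9 hESC replicate 2, either BG02 EB array, liver replicate 2 or liver replicate 3, the colon one also without liver replicate 1 and with 50 added, and both with dim probes removed and with normalization before the floor. Normalization by the median alone moved the median of all probes by 0.57 and none at all by 0.4, so the HCT116 differences stand relative to quantile normalization.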

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

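The tests of scaling and of left-over undifferentiated cells in this part were chosen after the result was seen, and the counts over other splits of the arrays were planned.

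The EB effect differed between BG02 and H9, by the interaction term, in 157 probes. The 10 largest differences were HES5 (-7.4), SERPINA3 (5.04), RHBDL3 (-4.78), CST1 (-4.72), FABP7 (-4.59), TLCD3B (-4.59), DCX (-4.58), IGFL2 (4.41), TAGLN3 (-4.38) and HOXA2 (-4.24), each a log2 difference of BG02 minus H9 effects from 2 arrays per group. CST1 stood higher in BG02 than in H9 already among the hESCs (5.18). Of the gene lists, secreted hepatocyte genes (median 1.66) and visceral endoderm genes (1.34) were higher in the BG02 effect, and neural ectoderm (-1.47), HOX (-0.53) and neural crest genes (-0.41) lower, each by camera and fry and none with an estimated correlation.

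The pattern to weigh is secreted hepatocyte genes up and neural genes down in BG02 EB-derived cells against H9 ones. Visceral and yolk sac endoderm genes went up as well (median 1.34). Their list stood at a mean log2 level of 9.83 in BG02 EB and 8.14 in H9 EB, and at 12.2 in adult liver. These lists therefore cannot tell liver from yolk sac endoderm. Under each of 4 scalings the hepatocyte and neural medians lay at least 0.75 outside the medians of 1000 sets of probes matched to them in level. The hepatocyte medians were 1.33 to 1.66 and the neural ones -1.38 to -1.59. These values argue against scaling that acts alike on probes of the same mean level as the whole cause. The match was on the mean over the hESC and EB-derived arrays, so a distortion of bright probes in some arrays alone was not tested. Fewer undifferentiated cells in the BG02 EB-derived arrays would raise every differentiated list together, while the neural list went down (-1.47, and -1.75 to -0.889 with single arrays left out) and the pluripotency list differed by a median of 0.02 between the EB-derived groups, so this alone cannot give the pattern. A difference between the lines and one between single cultures stay open and untested, since line and culture cannot be separated with 2 arrays per group. Between these arrays the SD on log2 was 0.71 in H9 EB and 0.13 in BG02 EB for the neural list, and 0.25 and 0.54 for the secreted hepatocyte list.

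Other splits of the same arrays were counted for the results with at least 3 arrays per side, in fits of 2 groups on those arrays alone. For liver against hESC, 1 of 35 splits of 7 arrays, the real one, gave as many changed probes (6348, against a highest of 0 in the others). For EB-derived cells against hESC over both lines it was also 1 of 35 splits of 8 arrays (3720, against a highest of 6). Every other split put both kinds of arrays on the same side, which widens the spread within it and leaves few calls. The arrays may also be technical repeats, so these counts cannot exclude a random grouping.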

How the results depend on the processing

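Quantile normalization before the floor, the EB effect from BG02 and median centring for lists were added after the data were seen, and the rest was planned. Counts for both EB comparisons over hESC, liver and HCT116 stayed within 1.5 times under every alternative but those given here. The spread from the arrays compared alone left 635 probes for endoderm, 748 for EB in H9, 36 for the interaction, 1077 for endoderm against EB, 2 for BG02 against H9 hESC and 1 for BG02 against H9 EB. The hESC line count was also 182 without further normalization, 190 with median centring and 225 with the replicate block, and the overlap of endoderm and EB effects 709 without further normalization. Fits on the arrays compared alone have fewer residual degrees of freedom than the 8 of the full fit. That by itself lowers the power to call probes, and whether those arrays also vary more was not tested. For the other changes the cause was not tested. Of 132 list calls 38 held with an estimated correlation, where the median of 0.044 for liver-high probes in endoderm had p = 0.07.

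Leaving out 1 array gave 767 to 2637 probes for endoderm, 2835 to 4436 for EB in H9, 2467 to 4259 for EB in BG02, 54 to 808 for the interaction, 1409 to 2929 for endoderm against EB, 47 to 1820 for BG02 against H9 hESC, 267 to 840 for BG02 against H9 EB, 449 to 1719 for the overlap and 0.429 to 0.773 for the carried-over line difference (r). The mesenchyme list in BG02 against H9 EB turned from 0.404 to -0.139 (adjusted p = 0.754) without H9 EB replicate 2, in a range up to 0.727. No named gene past the threshold changed its sign, and no other named gene passed with the opposite sign. Of 890 gene calls 187 were lost with the arrays compared alone, 72 with 50 added, 42 without further normalization and 40 with 1 added. Replicate numbers did not pair the arrays of most groups: of 21 pairs of groups 1 correlated over 0.1 in its deviations, and 2 under -0.1. The first was H9 EB with BG02 EB (0.235). The others were H9 hESC with BG02 hESC (-0.304) and BG02 hESC with H9 EB (-0.102). All lie among the groups of the line and interaction comparisons, and a shared preparation of those arrays stays open. With the replicate block endoderm had 1728 probes, EB in H9 3906, EB in BG02 3728 and the interaction 113, 35 gene calls were lost, POU5F1 in endoderm and FOXA2 between the hESC lines among them, and so were the colon and chromatin lists in HCT116. With no detection p-values, levels near the floor bear no ranking.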

Other observations

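The test of undifferentiated cells left in endoderm was chosen after the result was seen, and the correlation of line differences was planned.

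Some single genes stood high in HCT116 without their lists passing. Besides MAGEB2, PRAME (4.68, with a second probe at 0.81 that did not pass), MAGEA3 (4.24) and MAGEA6 (2.29), all cancer-testis antigens, were higher than in hESCs, 5 of 20 in that list against 2 lower, and the list did not pass (median -0.02, mean 0.81, adjusted p = 0.286). The fetal globins HBG1 (4.62) and HBG2 (4.58) rose beside HBE1, and HBA1 rose by 1.82, in an endothelial and blood list of 20 genes that did not pass (6 higher, 1 lower, median 0.04, adjusted p = 0.286). The imprinted genes SNRPN and NDN (-5.47) of one cluster were low in HCT116, with SNURF, while PHLDA2 (4.07) and PLAGL1 (2.05) were higher, and that list of 17 did not pass either (2 higher, 6 lower, 2 and 7 over the list alone, adjusted p = 0.286).

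In the chromatin list 6 of 16 genes fell and 1 rose with EB differentiation in each line, and its call was lost with an estimated correlation (adjusted p = 0.107 in H9 and 0.113 in BG02). JARID2, a partner of the Polycomb complex, fell (-2.57 in H9 and -3.23 in BG02), as did the helicase HELLS (-3.37 and -3.34) and the demethylating enzyme TET1 (-2.84 and -2.91). FOS fell in EB-derived cells of H9 (-4.79) and BG02 (-4.68), as did EGR1 (-3.94 and -3.58). Their list of 14 immediate early genes did not pass, with 1 rise and 5 falls in H9 (median -0.04, adjusted p = 0.307) and 0 and 5 in BG02 (median -0.28, adjusted p = 0.151).

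The BG02 EB samples carry a label naming H9 as the starting cells. If they had been grown from H9, the probes that differ between the hESC lines would show no matching difference after EB differentiation, with a correlation inside the permuted range. The correlation was 0.623, and 0.429 to 0.773 with single arrays left out, above the highest permuted value of 0.2, which argues against a wrong line and leaves the titles standing. CHCHD2, for one, differed by -7.39 before and -8.88 after.

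POU5F1 kept 22.1% of its H9 hESC intensity in endoderm (9.98 to 39.7% between extremes), or 6.98% on its second probe (2.82 to 15.4%), and NANOG 35% (29.9 to 40.5%). Undifferentiated cells left in the sort could bring such levels, but would bring their other abundant transcripts in the same share. Of 76 probes bright in BG02 hESCs (log2 of at least 9) and lower by at least 3 in BG02 EB-derived cells, 5.26% lay, in every H9 array, below the share of the first POU5F1 probe (CNMD 2.28%, FOS 3.81%, CAMKV 5.57%, FOSB 5.83%), 0% below that of the second, and the median probe kept 42.3%. Both shares are under the 10% that would have excluded left-over cells, and the 4 genes include FOS and FOSB, which respond to handling. For POU5F1, left-over cells and remaining expression in endoderm therefore cannot be told apart here. NANOG kept at least 29.9%, above CNMD (at most 4.2%), CAMKV (at most 9.79%) and the second POU5F1 probe (at most 15.4%). Its range overlapped that of the first POU5F1 probe. These values come from few of the 76 probes, no bound was set for NANOG, and its mean of 35% lies below the median probe (42.3%). CNMD and CAMKV lay below the first POU5F1 probe too, which was left undecided. For NANOG, left-over cells and remaining expression therefore cannot be told apart either. The endoderm arrays themselves differed in POU5F1 (SD 1.01 on log2).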
